A study of Mus musculus with 8 samples.

How the data were processed

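RNA was sequenced from Scid.adh.2c2 cells, a mouse pro-T cell line, in 8 libraries. They form 4 groups of 2: cells given a mock retrovirus, a retrovirus carrying wild-type Runx1 (Runx1 WT), one carrying a construct labelled Runx1 DN, and one carrying Satb1. Per the labels' protocols, infected cells were sorted 2 days after infection, RNA came from 300000 cells, libraries were made with a kit that does not mark the strand, and single reads of 50 nt were sequenced. The labels do not spell out DN, which in work on Runx proteins usually stands for dominant negative, and do not say which part of Runx1 the construct holds.

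Per the file headers, the authors counted reads over the exons of each gene with HOMER, without adjusting for length or depth, merged the transcripts of a gene, and used the mm9 mouse build. The deposited values are whole-number read counts, which sum to a different total in each library, although the table is named for another unit. Per the submitters' processing notes, the tools were Trimmomatic 033, STAR 2.4.0, RSEM 1.2.25, HOMER and edgeR 3.6.8. The authors' deposited table also holds, for each construct against mock, a log2 fold change, a p-value and an adjusted p-value that HOMER obtained from edgeR, per the file headers. Coordinates are mm9, as the table gives them, and the reference genome of another build was not used here.

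The table lists 24505 genes, of which 18438 had a count in any library. Library totals ran from 23624498 to 33093330 counts. A gene with no count in a library could still be present at up to 3 counts, 0.0953 to 0.125 CPM (counts scaled by library total and TMM factor) depending on the library. Such floors and all counting intervals (95% level) cover counting error only, since reads without molecular identifiers are not independent molecules. Of the rows above 0, 2860 shared all 8 counts with another row, 48 of them among the genes tested, and 2995 genes tested overlapped the span of another row. Counts did not use strand, so overlapping and antisense genes cannot be separated, and genes with near-identical copies (serum amyloid A, granzyme, Oas, Ifit and ribosomal protein families) are uncertain to the extent that reads were split between copies.

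From the counts, 12699 genes passed edgeR's filterByExpr (minimum count 10, minimum total count 15). Libraries were scaled by TMM, and edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) was fitted to all 8 libraries with group means only, leaving 4 residual degrees of freedom. The common biological coefficient of variation was 0.0818 and the prior degrees of freedom 5.84. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. The comparisons were Runx1 WT, Runx1 DN and Satb1 each against mock, and Runx1 WT against Runx1 DN. CPM values are means ± SD over 2 libraries on the TMM scale. Fold changes against a group with no counts are given as lower bounds, with 3 counts over the group put in place of 0.

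In addition, 25 gene lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and the rotation test fry were run beside it. Camera with an estimated correlation rests on the 4 residual degrees of freedom, so a call lost there is not thereby shown to be false. For T lineage genes the estimate was below the preset in every comparison (-0.035 to -0.029). The lists covered T lineage identity, pre-TCR and recombination, Notch response, stem and progenitor regulators, myeloid, B lineage, NK, ILC and cytotoxic genes, erythroid, mast and megakaryocyte genes, thymocyte maturation and migration, Runx family and cofactors, reported Satb1 targets, cytokine receptors and signalling, T cell receptor feedback, adhesion and cytoskeleton, S phase, G2/M, cell cycle inhibitors and D cyclins, p53 targets, the Bcl2 family, interferon response, ATF4 and unfolded protein response, glycolysis and hypoxia, cholesterol synthesis, ribosomal proteins, and RNA quality transcripts. Some lists share members, so their calls are not separate results. Runx3, for example, is in the thymocyte maturation, Runx family and Satb1 target lists. Il2ra is in the Notch response, cytokine receptor and Satb1 target lists. Genes named in the text are, per comparison, the 10 with the largest positive and the 10 with the largest negative fold change among those past the threshold whose libraries did not overlap between groups and whose higher group reached a mean of 2 CPM, leaving out predicted models. The rank uses fitted fold changes, which are no bounds for genes without counts in a group. Runx1 and Satb1 are always named, as are up to 4 members with the smallest adjusted p of each list that was called or had at least 3 members past the threshold. Genes outside this rule are marked where they appear.

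The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The plan provided for a test on log2 RPKM values or on counts, and the count test was used because the table holds counts. The alternatives were no filter, a filter at 5 RPKM in 2 libraries, DESeq2 size factors, quantile normalization, the 4 libraries of a comparison alone, a replicate block, DESeq2 1.42.0 as the test, robust empirical Bayes, stricter thresholds and each library left out. Scaling by library size alone, and leaving out the mock and Satb1 libraries numbered 2, were added after seeing the data.

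The steps were tested on simulated counts for 12699 genes, drawn from the mock means and the real library sizes. The filter was applied again, and a changed gene that it dropped counts as not recovered. The recoveries below therefore mix dropped genes with genes that the test missed. Of these genes 67, 67 and 66 were changed 1.5-fold, 2-fold and 4-fold. A planted list of further genes was raised 1.5-fold, and its calls are in the totals but are not counted as false. For Runx1 WT against mock, 65.7% of genes changed 1.5-fold, 77.6% changed 2-fold and 89.4% changed 4-fold were recovered, and 15 of 183 calls were false. For Runx1 DN against mock the recoveries were 53.7%, 79.1% and 89.4%, with 5 of 168 calls false. For Satb1 against mock they were 62.7%, 83.6% and 90.9%, with 17 of 190 false, and for Runx1 WT against Runx1 DN 65.7%, 80.6% and 90.9%, with 22 of 197 false. In that run the false share thus reached 11.2%, above the nominal level. For Runx1 WT against mock 70.7% of the genes tested were called, far more than were changed in the simulation. The simulated false shares may therefore not carry over.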

Results

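The data are 8 libraries of sorted Scid.adh.2c2 cells, 2 from each of 4 groups (mock, Runx1 WT, Runx1 DN and Satb1). The series title concerns PU.1 and the transcription factors it redirects in early T cells. These libraries address what added Runx1, the Runx1 DN construct or added Satb1 does to expression in the cell line. Library totals were 27077550 and 32950470 counts for mock, 26866359 and 26504378 for Runx1 WT, 23624498 and 27135363 for Runx1 DN, and 29551987 and 33093330 for Satb1. The labels do not say that replicates came from separate cultures or infections, so p-values measure only the spread between these samples, which may be technical. Within each group the libraries differed by 10.8 to 25.2 times the chi-square that counting noise gives per degree of freedom, so no library was a copy of another.

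The transduced genes were read first. Runx1 (NM_001111021, chromosome 16, 92601711 to 92826319, minus strand, mm9) had 3643 and 4054 counts in mock, 214392 and 232610 in Runx1 WT, 509871 and 673390 in Runx1 DN, and 5263 and 5791 in Satb1. Its log2 fold change over mock was 5.90 ± 0.12 (SE, n = 2 per group) with Runx1 WT and 7.41 ± 0.13 with Runx1 DN, where Runx1 took 2.16% and 2.48% of all counts. Satb1 (NM_001163631, chromosome 17, 51875512 to 51965913, minus strand) had 10172 and 11816 counts in mock and 104312 and 125348 in the Satb1 group, a log2 fold change of 3.31 ± 0.08. Satb1 was lower than mock with Runx1 WT (log2 fold change -0.33 ± 0.08, adjusted p = 0.0032, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and with Runx1 DN (-0.88 ± 0.08, adjusted p = 2e-05). In the authors' deposited table the log2 fold changes were 5.80 and 7.40 for Runx1 and 3.31 for Satb1 in the groups given those constructs.

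**Figure D1:**
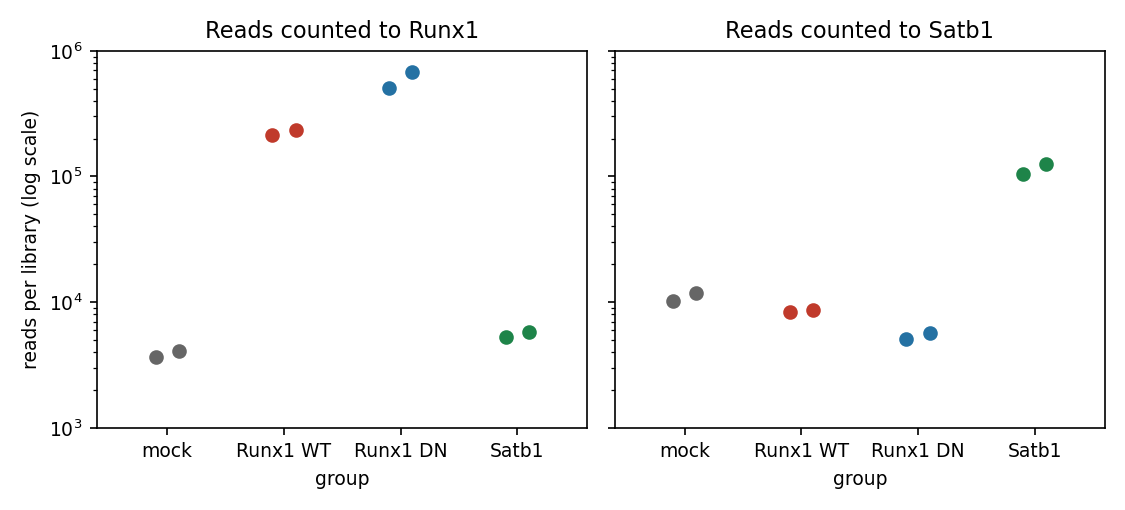
Reads counted to Runx1 (left) and Satb1 (right) in each library, on a log axis, with 1 point per library and 2 libraries per group. Runx1 lies at 214392 counts or more in the 4 libraries given a Runx1 construct and at 5791 or fewer in the others, and Satb1 lies at 104312 or more in the Satb1 libraries.

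With Runx1 WT, 15 of 16 genes of cytotoxic lymphocytes and 20 of 25 T lineage genes rose. All 22 S phase, all 22 G2/M and all 26 ribosomal protein genes and 19 of 21 glycolysis and hypoxia genes were lower than in mock. None of these list calls held with camera at an estimated correlation (adjusted p = 0.11 to 0.58). Fry passed all of them (fry adjusted p = 1.47e-06 to 0.0304), but it called every list with Runx1 WT. Cd7, a surface protein of T and NK cells, went from 1.16 ± 0.016 CPM (SD, n = 2) in mock to 679 ± 72 CPM, a log2 fold change of 9.19 ± 0.13 (SE). Itgae, the integrin alpha E chain, rose by 7.49 ± 0.20 and Il2rb, the beta chain of the interleukin 2 receptor, by 5.51 ± 0.31 on the log2 scale. Without mock replicate 2 Itgae stood at 8.09. Myc, a driver of growth, fell by 2.28 ± 0.09 and Rag1, part of the V(D)J recombinase, fell by 1.95 ± 0.11.

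Among the 10 genes with the largest fitted rises with Runx1 WT, 9 had no count in either mock library, and their folds are given as lower bounds, which do not follow the fitted order. Myt1, a zinc finger factor known from the nervous system, was at least 1050-fold higher (54.7 CPM), Saa2 at least 910-fold and Saa1 at least 135-fold higher (acute phase serum amyloid A proteins that resemble each other in sequence). The forkhead gene Foxs1 was at least 207-fold higher, the anion exchanger Slc26a4 at least 174-fold, and the lipase Abhd6 at least 153-fold. The collagen gene Col5a1 was at least 152-fold higher, the phosphate transporter Slc34a3 at least 122-fold and Ptchd3 at least 121-fold. Sec16b had 1 count in mock and a ratio of 2240 (95% counting interval 402 to 88600). The largest declines were Tmem45a (log2 fold change -5.40 ± 1.18), the fatty acid binding proteins Fabp4 (-4.92 ± 0.66) and Fabp5 (-3.59 ± 0.30), and the hypoxia-inducible Ankrd37 (-4.51 ± 1.14), Ndrg1 (-3.83 ± 1.26) and Bnip3 (-3.19 ± 0.76). Also lower were the Wnt antagonist Sfrp5 (-3.53 ± 0.24), the imprinted RNA H19 (-3.31 ± 0.13), Exoc3l4 (-3.19 ± 0.16) and the peptide hormone gene Apln (-3.11 ± 0.70). Ndrg1 differed between the mock libraries, with 4382 and 43089 counts. Without mock replicate 2 its log2 fold change was -1.61 (adjusted p = 0.23), and those of Tmem45a, Fabp4, Ankrd37, Bnip3 and Apln were -4.43, -4.22, -3.01, -2.09 and -1.96. Without mock replicate 1 Ndrg1, Ankrd37, Bnip3 and Apln stood at -4.67, -5.23, -3.80 and -3.73, and without Runx1 WT replicate 1 Tmem45a stood at -6.31. The adjusted p of Ndrg1, 0.019, became 0.095 without Runx1 WT replicate 1 and 0.097 without Runx1 WT replicate 2. With robust empirical Bayes Ndrg1, Ankrd37, Bnip3 and Apln had adjusted p of 0.15, 0.078, 0.066 and 0.051.

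Of 16 NK, ILC and cytotoxic genes measured, 15 rose and 1 fell with Runx1 WT (median log2 fold change 3.54, camera adjusted p = 7.42e-11, adjusted p = 0.11 with an estimated correlation). Gzmb, encoding granzyme B, rose by 8.27 ± 0.34, Nkg7 by 6.95 ± 0.22, Tbx21, which encodes T-bet, by 3.67 ± 0.13 and Cd160 by 3.64 ± 0.14. Of 25 T lineage genes, 20 rose and 1 fell (median 0.91, camera adjusted p = 2.88e-06, adjusted p = 0.11 with an estimated correlation), among them Cd3g (1.75 ± 0.07) and Cd247 (1.29 ± 0.08). In the thymocyte maturation and migration list 15 of 19 rose and 2 fell (16 and 2 adjusted over the list alone; median 1.31, camera adjusted p = 2.8e-06, adjusted p = 0.12 with an estimated correlation). There S1pr1 stood at 7.09 ± 0.40, Ccr9 at 3.49 ± 0.18 and Runx3 at 3.06 ± 0.15. Mock held few counts of S1pr1 (1 and 10) and Gzmb (0 and 5), and without mock replicate 1 they stood at 6.35 and 7.41. S1pr1 stood at 9.29 without mock replicate 2. T cell receptor feedback genes rose in 12 of 18 cases and fell in 1 (13 and 1 adjusted over the list alone; median 1.28, camera adjusted p = 0.000252, adjusted p = 0.11 with an estimated correlation). There the phosphatase gene Dusp2 rose by 4.77 ± 0.13, and the inhibitory receptor gene Pdcd1 had a ratio of 631 (174 to 5210) over the few counts in mock. Pdcd1 stood at 9.13 (log2) in the main fit and at 8.32 without mock replicate 1. Of 19 cytokine receptor and signalling genes 13 rose and 3 fell (median 0.99, camera adjusted p = 0.00411, adjusted p = 0.26 with an estimated correlation). The Runx family list, which holds the transduced Runx1 itself, had 7 of 12 higher and 2 lower (median 0.99, camera adjusted p = 8.16e-05, adjusted p = 0.17 with an estimated correlation), with the corepressor genes Tle2 at 2.90 ± 0.12 and Tle3 at 1.52 ± 0.06. Of 14 myeloid genes 11 rose and 1 fell (12 and 1 adjusted over the list alone; median 2.15, camera adjusted p = 0.00381, adjusted p = 0.25 with an estimated correlation), including Fcer1g (4.76 ± 0.18) and Itgam (3.02 ± 0.20), both also used by NK cells. In the Bcl2 family 8 of 10 rose and 1 fell (median 0.68, camera adjusted p = 0.0476, adjusted p = 0.51 with an estimated correlation). The survival gene Bcl2 rose by 4.17 ± 0.21 and the proapoptotic Bbc3 by 1.83 ± 0.16. The Bcl2 family call was lost in 11 other settings, with adjusted p from 0.051 to 0.14; among libraries left out, these were either mock library (0.068 and 0.078), Runx1 WT replicate 1 (0.089), Runx1 DN replicate 1 (0.051) and either Satb1 library (0.065 and 0.064).

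All 29 interferon response genes were higher with Runx1 WT (median 1.96, camera adjusted p = 1.62e-11, adjusted p = 0.25 with an estimated correlation), for example Oas1a (3.86 ± 0.21), Irf7 (3.45 ± 0.15), Bst2 (1.76 ± 0.07) and Tap1 (1.76 ± 0.09). All 22 S phase genes were lower (median -1.21, camera adjusted p = 5.42e-15, adjusted p = 0.17 with an estimated correlation). The 22 G2/M genes were all lower as well (median -1.23, camera adjusted p = 8.2e-13, adjusted p = 0.12 with an estimated correlation). Of these, Mcm3 stood at -1.54 ± 0.07, Rrm2 at -1.50 ± 0.08, Bub1b at -1.67 ± 0.07 and Ccnb1 at -1.38 ± 0.07. All 26 ribosomal protein genes were lower (median -0.86, camera adjusted p = 4.66e-07, adjusted p = 0.51 with an estimated correlation). In the same libraries the 6 RNA quality transcripts measured had list medians of 0.64 and 0.57 over the mock mean, against -0.02 and -0.07 with Satb1. They were Malat1, Neat1, Hsp90aa1, Hspa1a, Hspa1b and Fos, without any mitochondrial transcript of the list. Fos, Hspa1b and Hspa1a were low in mock (0.402, 0.692 and 0.981 CPM). RNA quality itself was not measured by these 6 genes. Of these 6, 3 rose and 1 fell with Runx1 WT (median 0.62, camera adjusted p = 0.826, fry adjusted p = 0.00422), among them the nuclear RNAs Neat1 (1.52 ± 0.12) and Malat1 (1.28 ± 0.13). Of 18 cholesterol synthesis genes 14 were lower (median -0.67, camera adjusted p = 0.00187, adjusted p = 0.52 with an estimated correlation). Of 15 Notch response genes 10 fell and 4 rose (median -1.03, camera adjusted p = 0.000694, adjusted p = 0.23 with an estimated correlation). Here Nrarp stood at -2.65 ± 0.12, Ptcra at -1.96 ± 0.11 and Il2ra at -1.03 ± 0.06. ATF4 and unfolded protein genes were lower in 8 of 15 cases and higher in 1 (median -0.33, camera adjusted p = 0.0472, adjusted p = 0.58 with an estimated correlation). That call was lost with the stricter filter (0.11), quantile normalization (0.19) and without Runx1 WT replicate 2 (0.081).

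Of 21 glycolysis and hypoxia genes 19 were lower with Runx1 WT and 1 was higher (median -2.08, camera adjusted p = 0.00187, adjusted p = 0.58 with an estimated correlation). Pdk1 stood at -2.54 ± 0.26, Eno1 at -2.37 ± 0.30 and Ldha at -2.32 ± 0.28. The replicates of mock and of Satb1 stood apart in these genes. Mock replicate 2 lay above mock replicate 1 by a median of 0.77 (log2), with all 21 members higher. Satb1 replicate 2 lay above Satb1 replicate 1 by 1.04, with 20 of 21 higher. In the Runx1 groups the same difference was -0.11 (WT) and 0.07 (DN). Without the mock and Satb1 libraries numbered 2, the list median with Runx1 WT was -1.50.

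The other lists were not called with Runx1 WT. Pre-TCR and recombination genes were higher in 5 and lower in 4 of 14 cases, with Spib at 5.75 ± 0.20. Stem and progenitor regulators were higher in 3 and lower in 1 of 7, with Kit at 4.85 ± 0.36. B lineage genes were higher in 4 and lower in 1 of 7 (5 and 1 adjusted over the list alone). Among them Cd74 stood at 4.21 ± 0.21. Erythroid, mast and megakaryocyte genes were higher in 6 and lower in 1 of 9, and reported Satb1 targets higher in 8 and lower in 4 of 13 (Foxp3 3.10 ± 0.09). Adhesion genes were higher in 9 and lower in 2 of 14, and cell cycle inhibitors and D cyclins higher in 8 and lower in 3 of 14 (Rbl2 2.38 ± 0.12, Cdk6 -1.51 ± 0.09). The p53 targets were higher in 9 and lower in 2 of 15 (Trp53inp1 1.89 ± 0.08). For lists where no second pair of counts is given, the counts adjusted over the list alone were the same.

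In total 8975 of 12699 genes passed the edgeR quasi-likelihood test at an adjusted p under 0.05 for Runx1 WT against mock, 4943 higher and 4032 lower, and 3663 of them changed at least 2-fold. The authors' deposited table has 8728 genes under that threshold, of which 8144 passed in both with the same sign. The median log2 fold change of all genes was 0.10, and 0.22 with scaling by library size alone and -0.09 with quantile normalization, so the balance of higher and lower genes depends on scaling. The split was 5651 higher and 3436 lower with library size alone, and it reversed to 4094 higher and 4883 lower with quantile normalization. Without the mock and Satb1 libraries numbered 2 the count was 7941.

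**Figure D2:**
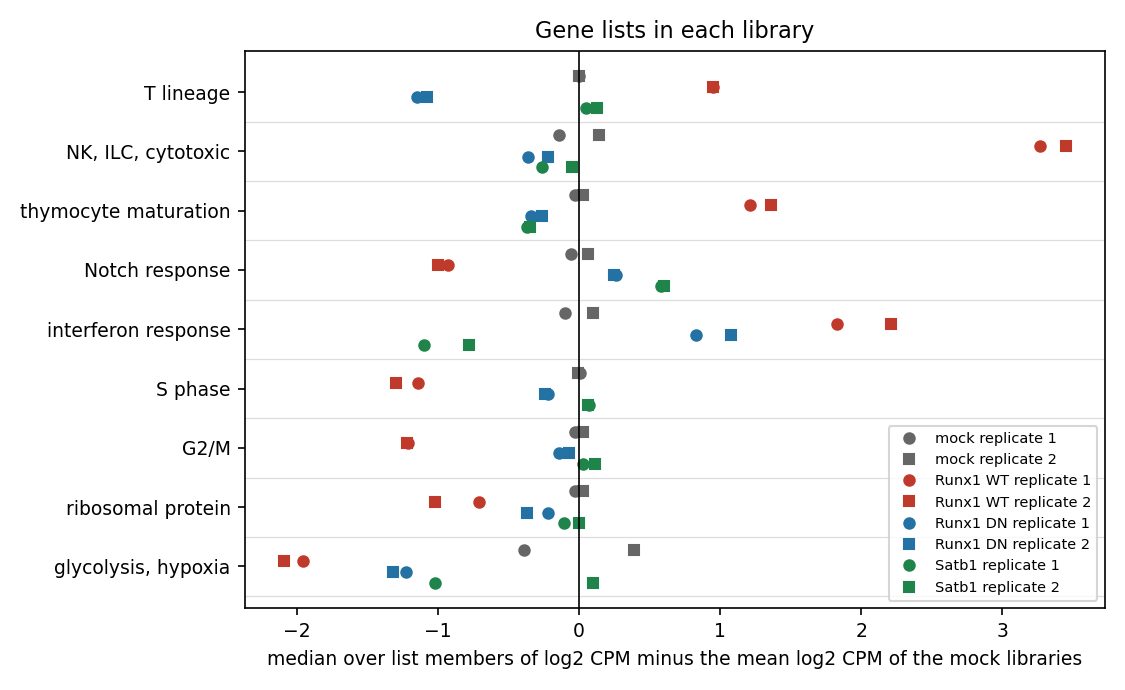
For 9 gene lists, each point is 1 library: the median over the list's members of log2 CPM minus the mean log2 CPM of the mock libraries, coloured by group, with circles for replicate 1 and squares for replicate 2. The interferon list lies at 1.83 and 2.21 in the Runx1 WT libraries, 0.83 and 1.08 in Runx1 DN and -1.10 and -0.78 in Satb1, while the glycolysis and hypoxia list separates the replicates of mock (-0.39 and 0.39) and of Satb1 (-1.02 and 0.10).

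With Runx1 DN, 20 of 25 T lineage genes fell, a call that held with an estimated correlation (adjusted p = 0.0098). Of 14 myeloid genes 10 rose, a call that did not hold (adjusted p = 0.17 with an estimated correlation). Tcf7, which encodes the T cell factor TCF-1, went from 1230 CPM in mock to 191 CPM (log2 fold change -2.69 ± 0.08), and Il7r, the interleukin 7 receptor, from 107 ± 9.4 CPM (SD, n = 2) to 7.47 ± 1.1 CPM (-3.84 ± 0.17). Il2ra, encoding CD25, fell by 2.96 ± 0.07 and Rag1 fell by 3.81 ± 0.12. Spi1, which encodes PU.1, rose from 0.64 ± 0.58 to 17.2 ± 2.3 CPM (4.67 ± 0.41), with 4.02 without mock replicate 1 and 6.21 without mock replicate 2.

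The largest fitted rises with Runx1 DN included P2ry6, a UDP receptor, at least 82.5-fold higher than mock, Ldb2 at least 70.2-fold, Ush1c at least 69.1-fold and the growth factor gene Hgf at least 42.7-fold, all without a count in mock. Igsf1, with 0 and 10 counts in mock, rose by 9.27 ± 0.30 (8.40 without mock replicate 1), the keratin gene Krt17 by 7.99 ± 0.21 and the proteoglycan gene Cspg4 by 7.52 ± 0.30. The cytokine gene Il1b had a ratio of 669 over mock (95% counting interval 120 to 26500), Otog 222 (75.7 to 1080) and the fatty acid receptor Ffar2 196 (53.8 to 1620). On the log2 scale Il1b went from 9.06 to 8.10 without mock replicate 2. Without mock replicate 1 Otog went from 7.67 to 8.30 and Ffar2 from 7.44 to 6.63. The largest declines were Ndrg1 (-6.59 ± 1.49), Fbln2 (-5.14 ± 0.20), Slc22a3 (-5.06 ± 0.22), Hivep3 (-4.85 ± 0.16), Gipr (-4.66 ± 0.76), Bnip3 (-4.50 ± 0.85), Il17rb (-4.37 ± 0.10), Ly6d (-4.31 ± 0.38), Slc16a5 (-4.29 ± 0.14) and Pck1 (-4.22 ± 0.39). Without mock replicate 2 the log2 fold changes of Ndrg1 and Bnip3 were -4.37 and -3.40, and without mock replicate 1 they were -7.43 and -5.12. Without Runx1 DN replicate 1 Gipr and Pck1 stood at -5.98 and -4.88, and without Runx1 DN replicate 2 Gipr stood at -3.91. The adjusted p of Ndrg1, 0.007, became 0.057 without Runx1 DN replicate 1 and 0.054 without Runx1 DN replicate 2. With robust empirical Bayes those of Ndrg1 and Bnip3 were 0.099 and 0.063.

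Of 25 T lineage genes 20 fell with Runx1 DN and 1 rose (median -1.03, camera adjusted p = 1.84e-21). This call held with an estimated correlation (adjusted p = 0.0098), where the estimate was -0.031, below the preset of 0.01. Thy1 stood at -2.29 ± 0.08, Lck at -2.01 ± 0.07 and Ets1 at -1.60 ± 0.07. Of 14 myeloid genes 10 rose and 2 fell (median 2.73, camera adjusted p = 5.74e-07, adjusted p = 0.17 with an estimated correlation). There Tyrobp stood at 5.42 ± 0.29 and the inhibitory Fc receptor Fcgr2b at 5.05 ± 0.40. Among 13 reported Satb1 targets 5 fell and 2 rose (6 and 2 adjusted over the list alone; median -0.36, camera adjusted p = 5.42e-05, adjusted p = 0.12 with an estimated correlation). Interferon response genes were higher in 26 of 29 cases and lower in 2 (median 0.97, camera adjusted p = 1.23e-09, adjusted p = 0.39 with an estimated correlation). Of these, Oasl2 stood at 2.85 ± 0.28, Gbp2 at 1.86 ± 0.14 and Irf1 at 0.90 ± 0.08. S phase genes were lower in 14 of 22 cases (16 adjusted over the list alone; median -0.24, camera adjusted p = 0.0169, adjusted p = 0.62 with an estimated correlation). Cholesterol synthesis genes were lower in 7 of 18 (9 adjusted over the list alone; median -0.29, camera adjusted p = 0.00989, adjusted p = 0.60 with an estimated correlation), and ribosomal protein genes in 13 of 26 (15 adjusted over the list alone; median -0.31, camera adjusted p = 0.00508, adjusted p = 0.68 with an estimated correlation). With quantile normalization the S phase and ribosomal protein calls ended (medians -0.13 and -0.07, adjusted p = 0.18 and 0.39). Beside these, the same 6 transcripts of the RNA quality list, with no mitochondrial one among them, had list medians of 0.82 and 0.75 in the Runx1 DN libraries. Of them 4 rose and none fell (5 and 0 adjusted over the list alone; median 0.84, camera adjusted p = 0.0787, fry adjusted p = 0.00152), with Malat1 at 1.02 ± 0.13 and Neat1 at 0.61 ± 0.12.

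Glycolysis and hypoxia genes were lower than mock in 17 of 21 cases with Runx1 DN (18 adjusted over the list alone; median -1.33, camera adjusted p = 0.000238, adjusted p = 0.60 with an estimated correlation). Here Hk1 stood at -1.41 ± 0.14 and Ldha at -1.57 ± 0.27. These are the genes in which the mock libraries differed from each other by 0.77, and without the mock and Satb1 libraries numbered 2 the median was -0.78.

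A further 7 lists were called with Runx1 DN at the preset correlation but lost their call in several other settings. NK, ILC and cytotoxic genes fell in 6 of 16 cases and rose in 2 (Gzma -3.66 ± 0.11, camera adjusted p = 0.00989), and thymocyte maturation genes fell in 9 of 19 and rose in 5 (10 and 6 adjusted over the list alone; 0.0128). Cytokine receptor genes fell in 9 of 19 and rose in 6 (9 and 7 adjusted over the list alone; 0.0169), and adhesion genes fell in 7 of 14 and rose in 2 (7 and 3 adjusted over the list alone; Lgals1 -2.06 ± 0.09; 0.0188). B lineage genes rose in 3 of 7 cases and fell in 1 (Cd22 4.61 ± 0.17, camera adjusted p = 0.0209). Of 15 p53 targets, 6 rose and none fell (6 and 1 adjusted over the list alone; Trp53inp1 1.93 ± 0.08; 0.0263). With an estimated correlation the adjusted p was 0.42 for adhesion genes and 0.39 for the other 5 lists. With no filter on low counts (camera adjusted p = 0.08 to 0.8) and with a replicate block (0.071 to 0.82) all 7 calls ended. Without Runx1 WT replicate 1 the camera adjusted p of these lists was 0.11 (NK and thymocyte), 0.44 (cytokine), 0.06 (adhesion), 0.12 (B lineage) and 0.075 (p53). Without Runx1 WT replicate 2 it was 0.11 (NK and thymocyte), 0.45, 0.062, 0.12 and 0.074. Without mock replicate 1 that of p53 targets was 0.074. For the Runx family list, 3 of 12 rose and 3 fell. Camera gave an upward call (adjusted p = 0.0263, adjusted p = 0.39 with an estimated correlation) with a mean of 0.43 that includes the transduced Runx1, while the median was -0.06. Its adjusted p without mock replicate 1, mock replicate 2, Runx1 WT replicate 1 and Runx1 WT replicate 2 was 0.10, 0.12, 0.94 and 0.91.

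The remaining lists were not called with Runx1 DN. Notch response genes were higher in 7 and lower in 4 of 15 cases (7 and 5 adjusted over the list alone). Among them Hes5 stood at 1.88 ± 0.14 and Nrarp at 1.42 ± 0.11. Pre-TCR and recombination genes were higher in 5 and lower in 4 of 14, where the median (0.18) and mean (0.08) were above 0 and the camera direction was down. G2/M genes were lower in 5 of 22 (2 adjusted over the list alone). Stem and progenitor regulators were higher in 2 and lower in 2 of 7 (2 and 3 adjusted over the list alone), and erythroid, mast and megakaryocyte genes in 2 and 2 of 9, with a camera direction down against a median of 0.02 and a mean of 0.36. Counts higher and lower were, in the same order, for T cell receptor feedback genes 7 and 3 of 18, cell cycle inhibitors and D cyclins 4 and 2 of 14, the Bcl2 family 6 and 1 of 10, and ATF4 and unfolded protein genes 1 and 2 of 15 with a camera direction down against a mean of 0.10. The RNA quality list, given above, was not called either.

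For Runx1 DN against mock, 4375 genes passed the edgeR quasi-likelihood test, 2227 higher and 2148 lower, and 1448 changed at least 2-fold. The authors' deposited table has 4103, with 3804 in both and of the same sign. With scaling by library size alone the split was 2901 higher and 1515 lower, and with DESeq2 size factors 2103 higher and 2436 lower. The count was 2715 without the mock and Satb1 libraries numbered 2, and 2908 without Runx1 DN replicate 1.

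With Satb1, 17 of 29 interferon genes fell, and 8 of 15 Notch response genes and 7 of 25 T lineage genes rose. None of these list calls held with an estimated correlation (adjusted p = 0.15, 0.15 and 0.084). Cxcl10, an interferon-inducible chemokine, fell by 3.31 ± 0.37 and Irf7 fell by 1.61 ± 0.15. Notch1 rose by 1.14 ± 0.10 (log2 fold change ± SE, n = 2 per group), Lef1, a T cell factor, from 93.6 to 415 CPM (2.15 ± 0.09) and Rag2 by 1.84 ± 0.20. Il7r fell by 2.31 ± 0.15.

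The largest fitted rises with Satb1, besides Satb1 itself, were Fcgbp (ratio 40.1 over mock, 95% counting interval 13.4 to 197), the prostaglandin D synthase gene Hpgds (3.84 ± 0.15), Cd7 (3.68 ± 0.14), and the lens crystallin genes Cryba4 (3.68 ± 0.17) and Crybb1 (3.20 ± 0.25). They also included Ifitm2 (3.50 ± 0.17), which belongs to an interferon-inducible family and is not in the interferon list, the long noncoding RNA Miat (3.33 ± 0.38), the kinase gene Camk2a (3.31 ± 0.27) and Sept4 (3.03 ± 0.33). Without mock replicate 2 Miat and Sept4 stood at 4.06 and 3.94, and without Satb1 replicate 2 Cxcl10 stood at -4.04. Fcgbp stood at 5.21 (log2) in the main fit and at 4.38 without mock replicate 1. The largest declines were the interferon-inducible GTPase genes Gvin1 (-3.96 ± 0.41), whose span overlaps other genes, and Iigp1 (-2.81 ± 0.22), together with Mpeg1 (-3.84 ± 0.48) and Cxcl10. Lower too were Ms4a4b (-2.80 ± 0.29), Ly6a, which encodes Sca-1 (-2.80 ± 0.22), the RNA binding protein gene Elavl4 (-2.61 ± 0.11), Cadm1 (-2.58 ± 0.19), the mast cell protease gene Cpa3 (-2.52 ± 0.19) and Thsd7b (-2.50 ± 0.16).

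Of 29 interferon response genes 17 fell with Satb1 and none rose (27 lower adjusted over the list alone; median -0.93, camera adjusted p = 1.64e-29, adjusted p = 0.15 with an estimated correlation). There Bst2 stood at -1.06 ± 0.07. Of 15 Notch response genes 8 rose and none fell (9 and 1 adjusted over the list alone; median 0.59, camera adjusted p = 4e-09, adjusted p = 0.15 with an estimated correlation). Of these, Nrarp stood at 0.95 ± 0.11, Dtx1 at 0.86 ± 0.10 and Notch3 at 0.77 ± 0.08. Of 25 T lineage genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.12, camera adjusted p = 1.77e-07, adjusted p = 0.084 with an estimated correlation). Here Cd2 stood at 1.34 ± 0.16 and Lck at 0.67 ± 0.07. Cholesterol synthesis was called upward with 1 of 18 genes past the threshold (3 adjusted over the list alone; median 0.17, camera adjusted p = 0.0199, adjusted p = 0.89 with an estimated correlation). Adhesion genes were called downward with 4 lower and 2 higher of 14 (median -0.04, camera adjusted p = 0.0304, adjusted p = 0.85 with an estimated correlation). Among them Ahnak stood at -1.96 ± 0.23 and Lgals1 at -1.02 ± 0.09. The adhesion call ended with a replicate block (camera adjusted p = 0.32) and with no filter (0.13). It also ended with the stricter filter (0.18) and with the 4 libraries compared alone (0.065). Without mock replicate 2 the adhesion median was 0.07 (adjusted p = 0.13), and without Runx1 WT replicate 1 or replicate 2 its adjusted p was 0.17 each.

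The other 20 lists were not called with Satb1. Thymocyte maturation genes were higher in 4 and lower in 5 of 19 cases (4 and 7 adjusted over the list alone). There Ccr4 stood at 1.62 ± 0.11. Pre-TCR and recombination genes were higher in 4 and lower in none of 14, with Rag1 at 1.00 ± 0.11. Cytokine receptor genes were higher in 2 and lower in 5 of 19 (3 and 5 adjusted over the list alone), and NK, ILC and cytotoxic genes higher in 3 and lower in 2 of 16 (4 and 2 adjusted over the list alone). Of these, Zbtb16 stood at 3.01 ± 0.24 and Gzma at -1.20 ± 0.09; the camera direction of the latter list was up against a median of -0.35. Counts higher and lower were 3 and 1 of 13 for reported Satb1 targets (3 and 4 adjusted over the list alone), 1 and 2 of 14 for myeloid genes (5 and 3 adjusted over the list alone; median 0.91, or 0.79 with genes without counts in a group at their bound), and 2 and 1 of 12 for the Runx family. They were 1 and 1 of 7 for B lineage genes, 0 and 1 of 7 for stem and progenitor regulators, 0 and 1 of 9 for erythroid, mast and megakaryocyte genes (1 and 2 adjusted over the list alone), 1 and 1 of 18 for T cell receptor feedback and 1 and 1 of 10 for the Bcl2 family (2 and 1 adjusted over the list alone). Reported Satb1 targets (median -0.03) and the Runx family (mean -0.12) had a camera direction of up, B lineage genes (median 0.02, mean 0.10) one of down, and stem and progenitor regulators one of down against a median of 0.23. No member passed for S phase, cell cycle inhibitors and D cyclins, ATF4 and unfolded protein, ribosomal protein, or glycolysis and hypoxia genes, where the Satb1 libraries differed from each other by 1.04 and the median against mock was -0.39 (camera adjusted p = 0.0793). Of G2/M genes 1 was higher, of p53 targets 1 was higher, and of RNA quality transcripts 1 was lower.

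For Satb1 against mock, 808 genes passed the edgeR quasi-likelihood test, 416 higher and 392 lower, and 335 changed at least 2-fold. The authors' deposited table has 1010, with 768 in both and of the same sign. With a replicate block 1265 genes passed. Runx1 stood at 0.45 ± 0.10 with an adjusted p of 0.027, which became 0.10 to 0.23 when any single mock or Satb1 library was left out. The count of genes was 524 without mock replicate 1, 430 without mock replicate 2, 478 without Satb1 replicate 1 and 314 without both libraries numbered 2.

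Set directly against each other, with fold changes that use no mock library, 23 of 25 T lineage and 15 of 16 cytotoxic genes were higher with Runx1 WT than with Runx1 DN, and 9 of 15 Notch response genes lower. With an estimated correlation only the first call of these 3 held (adjusted p = 0.0089, 0.10 and 0.25). Cd7 was higher with Runx1 WT than with Runx1 DN by 10.84 ± 0.15, Itgae by 8.64 ± 0.23, Il7r by 4.16 ± 0.17, Lck by 2.97 ± 0.07 and Tcf7 by 2.70 ± 0.08 (log2 ± SE, n = 2 per group). Genes lower with Runx1 WT than with Runx1 DN included H19 (-9.39 ± 0.14), Spi1 (-5.64 ± 0.46), Hes5 (-4.48 ± 0.17), Nrarp (-4.07 ± 0.12) and Cd22 (-3.80 ± 0.16). Runx1 itself, which Runx1 DN cells carried at more counts, stood at -1.51 ± 0.10.

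Ranked by fitted fold change, which is no bound for genes at 0 counts, the first differences toward Runx1 WT besides Cd7 were the incretin receptor gene Glp1r (at least 326-fold), Sdc2 (at least 304-fold), Foxs1 (at least 185-fold), Slc26a4 (at least 156-fold), the cystatin gene Cst7 (at least 133-fold), Saa1 (at least 121-fold) and Ptchd3 (at least 109-fold), all without a count in Runx1 DN. By ratio they were Saa2 (ratio 2450, 439 to 96700) and Sec16b (2010, 361 to 79500). On the log2 scale Saa2 went from 10.96 to 10.17 without Runx1 DN replicate 1. Sec16b went from 10.68 to 9.72 without Runx1 DN replicate 2. In the same ranking toward Runx1 DN the first differences were Mpdz (at least 157-fold), Man1c1 (at least 139-fold), Ush1c (at least 67-fold) and Sparcl1 (at least 54.1-fold), without a count in Runx1 WT. They also included Igfbp5 (-10.14 ± 0.33, with 0 and 5 counts in Runx1 WT, and -9.17 without its replicate 1), Igsf1 (-9.94 ± 0.32), H19, and by ratio the H19-overlapping Mir675 (1440, 257 to 56800), Filip1 (778, 266 to 3770) and Lbp (742, 133 to 29300).

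T lineage genes were higher with Runx1 WT in 23 of 25 cases and lower in 1 (median 2.22, camera adjusted p = 1.55e-22). This call held with an estimated correlation (adjusted p = 0.0089), where the estimate was -0.029, below the preset of 0.01. NK, ILC and cytotoxic genes were higher in 15 of 16 and lower in 1 (median 4.16, or 3.95 with bounds; camera adjusted p = 5.12e-14, adjusted p = 0.10 with an estimated correlation). Thymocyte maturation genes were higher in 16 of 19 and lower in 1 (median 1.82, camera adjusted p = 9.24e-10, adjusted p = 0.10 with an estimated correlation), and cytokine receptor genes in 15 of 19 and lower in 2 (median 0.98, camera adjusted p = 2.34e-05, adjusted p = 0.16 with an estimated correlation). Reported Satb1 targets were higher in 9 of 13 and lower in 1 (median 1.69, camera adjusted p = 0.000749), T cell receptor feedback genes in 10 of 18 and lower in 3 (median 0.89, 0.000749), both at an adjusted p of 0.10 with an estimated correlation. Interferon genes were higher in 21 of 29 and lower in 1 (median 0.99, camera adjusted p = 0.000749, adjusted p = 0.59 with an estimated correlation). Adhesion genes were higher in 8 of 14 and lower in none (median 0.31, camera adjusted p = 0.00256, adjusted p = 0.29 with an estimated correlation) and Runx family genes in 7 of 12 and lower in 3 (median 0.78, camera adjusted p = 0.026, adjusted p = 0.37 with an estimated correlation; without Runx1 DN replicate 1, 0.06). All 22 S phase and all 22 G2/M genes were lower with Runx1 WT (medians -0.97 and -1.10, camera adjusted p = 1.08e-10 and 7.19e-11, adjusted p = 0.25 and 0.13 with an estimated correlation). Notch response genes were lower in 9 of 15 and higher in 5 (median -1.46, camera adjusted p = 0.00103, adjusted p = 0.25 with an estimated correlation). With no filter the Notch and adhesion calls were lost, both at an adjusted p of 0.055. All 26 ribosomal protein genes were lower (median -0.55, camera adjusted p = 0.00103, adjusted p = 0.77 with an estimated correlation). That call ended with quantile normalization (median -0.25 where all genes stood at -0.12, adjusted p = 0.16).

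Lists not called between the constructs included myeloid genes (6 higher and 6 lower of 14) and B lineage genes (3 and 2 of 7), both with a camera direction of down against medians of 0.22 and 0.34. Cell cycle inhibitors and D cyclins (4 and 5 of 14) had a median of -0.05 and a mean of 0.18. Between the Runx1 constructs 8676 genes passed the edgeR quasi-likelihood test, 4420 higher with Runx1 WT and 4256 lower, and 3361 differed at least 2-fold. That split depends on scaling: it was 3847 higher and 5047 lower with quantile normalization, and 4277 and 4426 with DESeq2 size factors. The count was 8448 without the mock and Satb1 libraries numbered 2.

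Both Runx1 constructs were then compared gene by gene. Among genes tested, 1443 were higher with both constructs than in mock and 1211 lower with both. In opposite directions, 590 were higher with Runx1 WT and lower with Runx1 DN and 215 the reverse. Independent lists of the same sizes would share 867, 682, 836 and 707. Cd7 and Itgae are in the first of the opposite classes and H19 in the other. All 590 and all 215 passed the direct test between the constructs, which choosing them for opposite calls nearly ensures. Of the genes called in the same direction 916 of 1443 and 929 of 1211 passed it too, and of all genes 68.3%. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.231 and Spearman's rho 0.361. Simulated unchanged groups sharing the mock libraries gave 0.496 and 0.457. Those values come from shared noise alone, whereas changed genes add to the spread of the real fold changes. They therefore set no level for the observed r and rho. The simulated fits were also filtered again, which drops genes at or near 0 counts in mock. Their covariances thus cover fewer genes than the observed ones and set no like-for-like level. The covariance of the fold changes was 0.369 against 0.0231 in those simulations (20 draws), and without mock replicate 2 the r was 0.371. The covariance with Satb1 was 0.0838 for Runx1 WT (simulated 0.0227) and 0.165 for Runx1 DN (simulated 0.0228). Here r was 0.0949 and 0.248 (simulated 0.50 and 0.496, with the same limit). These r values rested on the settings: for Runx1 WT 0.221 without mock replicate 1, 0.31 without mock replicate 2 and -0.016 with the stricter filter, and for Runx1 DN 0.354, 0.451 and 0.11. Splitting the mock libraries would leave 1 per part, so part of the excess in the overlaps may come from the shared controls.

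**Figure D3:**
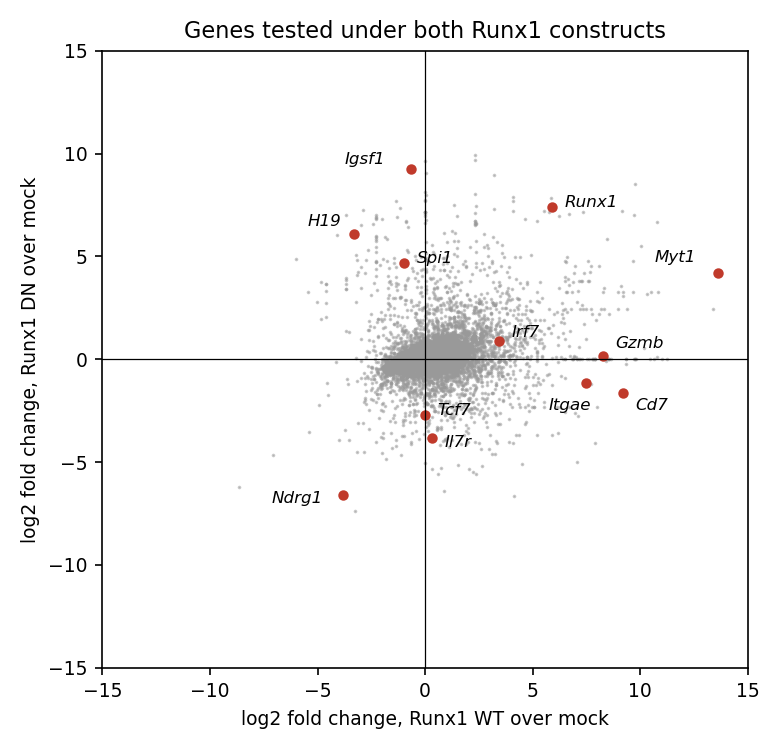
Each grey point is 1 of 12699 genes, at its log2 fold change over mock with Runx1 WT (x axis) and with Runx1 DN (y axis), with 12 genes marked in red. For genes without a count in a group, such as Myt1 in mock, the position is a fitted value and no bound. Cd7 (9.19 and -1.65) and H19 (-3.31 and 6.08) lie in opposite quadrants, and Irf7 (3.45 and 0.90) is higher with both constructs.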

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

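The tests against mock replicate 1 alone and the test of the amount of Runx1 transcript were chosen only after the results they concern had been seen, and the bound for the mock replicate tests was tightened after their values were known. The differences between groups below were tested directly with camera at its preset correlation, with Benjamini-Hochberg adjustment. A list is given among these differences only where both groups were called against mock, in opposite directions, and the direct test passed. A direct adjusted p under 0.05 was thus fixed by that choice and lends no further support. The calls of NK, thymocyte maturation and cytokine receptor genes with Runx1 DN were lost in several other settings.

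The groups differed in several gene lists, with 2 libraries per group. Runx1 WT lay above Runx1 DN by a list median (log2) of 2.22 for T lineage genes (adjusted p = 1.5e-22, adjusted p = 0.0089 with an estimated correlation), which fell with Runx1 DN and rose with Runx1 WT. The same direct comparison gave 4.16 for NK, ILC and cytotoxic genes (adjusted p = 5.1e-14, adjusted p = 0.1 with an estimated correlation), and 1.82 for thymocyte maturation genes (adjusted p = 9.2e-10, adjusted p = 0.1 with an estimated correlation). For cytokine receptor genes it gave 0.98 (adjusted p = 2.3e-05, adjusted p = 0.16 with an estimated correlation). Against Satb1, Runx1 WT lay at -1.69 for Notch response genes (adjusted p = 1.3e-06, adjusted p = 0.13 with an estimated correlation) and at 2.82 for interferon genes (adjusted p = 1.3e-19, adjusted p = 0.13 with an estimated correlation). For cholesterol synthesis genes it lay at -0.84 (adjusted p = 0.00015, adjusted p = 0.44 with an estimated correlation). Runx1 DN against Satb1 gave -1.55 for T lineage genes (adjusted p = 7.6e-32, adjusted p = 0.0045 with an estimated correlation) and 1.97 for interferon genes (adjusted p = 1.7e-28, adjusted p = 0.18 with an estimated correlation). For cholesterol synthesis genes it gave -0.5 (adjusted p = 0.00012, adjusted p = 0.44 with an estimated correlation).

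Glycolysis and hypoxia genes were lower than mock with both Runx1 constructs (adjusted p = 0.58 and 0.60 with an estimated correlation), while mock replicate 2 lay above mock replicate 1 by a median of 0.77. Against mock replicate 1 alone the list median was still -1.5 with Runx1 WT, further from 0 than the gap between the mock libraries accounts for. With Runx1 DN it was -0.77, no larger than that gap, so for Runx1 DN the construct and the difference between mock libraries cannot be told apart; under the bound first set, the spread between construct libraries, this value would have counted against the mock libraries as the cause. Libraries without a Runx1 construct spread further than the mock libraries alone. Satb1 replicate 1 lay at -1.02 over the mock mean, against -0.39 for mock replicate 1. On that scale the Runx1 WT libraries lay at -1.96 and -2.09, and the Runx1 DN libraries at -1.23 and -1.32. Under 3 other scalings the list median closest to 0 was -1.12. These scalings left the median of all genes between -0.088 and 0.22 with Runx1 WT, and between -0.02 and 0.085 with Runx1 DN. They could hardly have brought the list near 0. The value thus shows only that the choice among these scalings does not account for the decline. A difference in culture density or oxygen between dishes stays open, as does an effect of Runx1.

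Interferon genes were higher than mock with both Runx1 constructs (adjusted p = 0.25 and 0.39 with an estimated correlation). If the amount of Runx1 transcript alone set the rise, and if counts compare that amount between constructs whose Runx1 parts the labels do not give, Runx1 DN would show the larger one, but the list lay at 1.83 and 2.21 in the Runx1 WT libraries and at 0.83 and 1.08 in the Runx1 DN libraries, a median difference of 0.99 (adjusted p = 0.59 with an estimated correlation, fry adjusted p = 0.00459). Its bootstrap interval (0.52 to 1.75) treats the 29 members as independent. If counts compare amount between the constructs, amount alone is argued against by the separation of these 4 libraries, more than by that interval. Amount and construct differ together here, so a part played by amount beside the construct cannot be told apart. Of 7 tested markers of myeloid or B cells, 4 were higher with Runx1 WT (Cd74, H2-Aa, Tyrobp and Cd68), 5 with Runx1 DN (Cd74, H2-Aa, Tyrobp, Ctss at 4.02 and Cybb) and 3 with both, but without mock replicate 1 Cd74 and H2-Aa did not pass with Runx1 DN (adjusted p = 0.076 and 0.14), nor did Cd74 without Runx1 DN replicate 1 (0.079) or H2-Aa without either Runx1 DN replicate (0.077 and 0.11), while Cybb stood at -1.14 with Runx1 WT and 3.02 with Runx1 DN, and Lyz2 had 0 to 4 counts per library; yet 11 and 10 of the 14 genes of the myeloid list rose with Runx1 WT and Runx1 DN (medians 2.15 and 2.73, adjusted p = 0.25 and 0.17 with an estimated correlation), and B lineage medians were 1.33 and 1.00. Against the same abundant set of such cells in both groups stand only the markers that did not rise in both, and other cells in either group, a small share hidden by the baseline of H2-Ab1, myeloid genes expressed by the line itself, a response to the retroviral preparations, whose amounts the labels do not give, and an effect of the constructs stay open.

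Many genes changed the same way with both Runx1 constructs. The mock libraries they share add to that. With separate controls (Runx1 WT against Satb1, Runx1 DN against mock), which share no library, the covariance of fold changes was still 0.205. With the controls exchanged it was 0.286. Shared mock libraries alone would bring it to 0 or below there, so they are argued against as the whole source. The highest value of the simulated unchanged groups that share mock was lower, at 0.0252. Those simulations dropped genes at or near 0 counts in mock, which the 0.205 includes, so 0.0252 sets no level for it. Mock and Satb1 are not fully separate controls, since their replicate differences correlated by 0.39, and the simulated groups hold no such shared difference. A difference that mock and Satb1 share stays open for that reason. So do an effect of Runx1 that both constructs keep and an effect of retroviral load, and no value here separates them.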

How the results depend on the processing

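Leaving out the mock and Satb1 libraries numbered 2 and scaling by library size alone were chosen after seeing the data. Of 405 results for named genes, 361 kept their direction and side of the threshold in every setting, and of 49 called lists 33 did. The transduced genes kept both in all 40 other and 32 leave-one-library-out results. Named genes left the threshold in 74 leave-one-out and 66 other results and newly passed it in 6 and 13, and lists left it in 27 and 33, besides 1 of each kind that turned direction and left it. Leaving a library out leaves a group with 1 library, assumed to vary like the other groups. The cause of the changes below was not tested. The alternative pseudocount was not run because the table holds counts.

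With a 2-fold minimum 3663 (Runx1 WT), 1448 (Runx1 DN), 335 (Satb1) and 3361 (Runx1 WT against Runx1 DN) genes passed, and at an adjusted p under 0.01 2680 with Runx1 DN and 408 with Satb1. Without the mock and Satb1 libraries numbered 2 the counts were 2715 with Runx1 DN and 314 with Satb1, and with the stricter filter 517 with Satb1. Leaving out 1 library gave 2908 (Runx1 DN replicate 1) to 4675 genes with Runx1 DN and 430 (mock replicate 2) to 839 with Satb1; without mock replicate 1 and Satb1 replicate 1 the Satb1 count was 524 and 478. A replicate block gave 1265 genes with Satb1 and 9 lists with Runx1 DN (ending the B lineage, NK, thymocyte, Runx family, cytokine, adhesion and p53 calls, adjusted p = 0.071 to 0.82), but the numbers were not taken to pair the libraries: replicate differences correlated by 0.07 to 0.19 between other groups, and by 0.39 between mock and Satb1. In those 2 groups replicate 2 lay higher in 21 and 20 of 21 glycolysis and hypoxia genes. The same held for 26 and 26 of 26 ribosomal protein genes, so a difference shared by number stays open for Satb1 against mock. With Runx1 WT and Runx1 DN replicate 2 lay higher in 0 and 4 of those 26. In mock, Runx1 WT, Runx1 DN and Satb1 it lay higher in 21, 26, 24 and 23 of 29 interferon genes. For ATF4 and unfolded protein genes the counts were 4, 1, 0 and 5 of 15. A difference by number is thus not excluded for the Runx1 groups either. With an estimated correlation 0 lists passed with Runx1 WT, 1 with Runx1 DN, 0 with Satb1 and 1 between the Runx1 constructs, and fry called 25 with Runx1 WT. With Satb1, library size scaling gave 8 lists and leaving out 1 library 4 to 8. The Runx family list with Runx1 DN turned direction in camera with no filter (median -0.09) and without Runx1 WT replicate 1 (adjusted p = 0.94); its medians leaving out 1 library were -0.17 to -0.05.

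The correlation of Runx1 WT with Runx1 DN fold changes was 0.323 with no filter, 0.173 with quantile normalization, 0.33 with the 4 libraries compared alone, 0.368 without the libraries numbered 2, and 0.2 to 0.371 leaving out 1 library. That of Runx1 WT with Satb1 was 0.284, -0.016 (stricter filter, reversed), 0.232 without the libraries numbered 2 and 0.055 to 0.31. That of Runx1 DN with Satb1 was 0.352 with no filter, 0.11 with the stricter filter, 0.34 and 0.177 to 0.451. Depth limits what can be seen of genes near 3 counts per library.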

Other observations

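The imprinted H19 and Igf2 genes, which lie near each other on chromosome 7, were singled out after their values were seen. H19 passed the test with each construct, and Igf2 with Runx1 DN. H19 rose by 6.08 ± 0.12 with Runx1 DN (log2 fold change ± SE, n = 2 per group, adjusted p = 1.7e-09) and by 1.25 ± 0.10 with Satb1, and fell by 3.31 ± 0.13 with Runx1 WT. Igf2 rose by 7.37 ± 0.30 with Runx1 DN and stood at -1.18 with Runx1 WT (adjusted p = 0.313) and 1.03 with Satb1 (adjusted p = 0.472). The reads of H19 and of Mir675, whose spans overlap, cannot be assigned to one or the other.

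A hypothesis chosen for testing was that neighbouring genes change together beyond read-through or overlapping transcripts, which may raise the fold changes of close pairs alike. For adjacent genes over 20 kb apart (5484 pairs), the Spearman correlation of fold changes was 0.134 for Runx1 WT against mock, above the highest of the shuffles of gene order (0.049). It was 0.156 for Runx1 DN (highest 0.038) and 0.133 for Satb1 (highest 0.053). Over 100 kb apart (2550 pairs) it was 0.085, 0.126 and 0.069, against highest shuffles of 0.063, 0.054 and 0.076, so Satb1 did not exceed them there. Read-through that ends within 20 kb is thus argued against as the whole source. Up to 5 kb apart the correlations were 0.234, 0.216 and 0.188 in the same order, higher than over 100 kb. Longer read-through was not tested and stays open, as do copies of a gene in tandem and properties shared by a region.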
